A study of Mus musculus with 6 samples.

How the data were processed

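RNA-seq was carried out on morula-like aggregates, 3-dimensional clusters that model the compacting mouse embryo and that are grown from mouse expanded pluripotent stem cells, a stem cell state with broad developmental potential. Per the labels' protocols, aggregates were kept at 37 °C with 5% CO2 and 20% O2. The 6 libraries are 3 from vehicle controls (DMSO) and 3 from cultures treated with perfluorooctanoic acid (PFOA), and the dose and the length of exposure are not given in the sources used here. Per the labels' protocols, 1.2 µg of TRIzol-extracted total RNA with an RNA integrity number above 8.0 was enriched for polyadenylated RNA and sequenced on a BGISEQ-500. The group and replicate number of each library come from its title. The labels do not say whether the 3 replicates of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

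The deposited table holds FPKM (fragments per kilobase of transcript, scaled by the mapped fragments of the library) for 18388 gene symbols, which the authors gave to 2 decimals with 1 column per library. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5 and the mouse build GRCm39. The step each tool was used for, the counting tool and the annotation are not given in the sources used here. FPKM divides by transcript length and by the library total, so a group of abundant transcripts that falls raises the FPKM of others, and a bias that acts by transcript length differs between genes. The absolute depth is unknown. The relative depth was sought from the lowest values above 0 of 129 genes, of which 44 to 58 per library could be used. The value taken as 1 read in a library was between 0.981 and 1.01 times the mean over libraries. Only values within 12% of a gene's smallest value above 0 were taken. That rule holds the ratio near 1 in advance, so it does not measure relative depth. Of the larger values of these genes, 62.6% lay within 0.15 of a whole multiple, so whole reads were not recovered and no count test was run. The rule for the lowest value was changed once after a first version fixed its own outcome.

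Symbols are written in upper case in the table and were matched without regard to case to mouse names; 18234 matched and 154 did not. Transcript length, GC content and shared 50-nt words came from GENCODE M21 transcripts, which are on another build, so no coordinates are printed. Of the named genes, Ctnnd1, Rps18, S100a4, Etv5, Cycs, Phb, Gpx4, Acaa1b, Acaca, Zscan4c and Gm2022 have at least 20% of their 50-nt words in transcripts of other genes, so their values are uncertain where the authors' counting could split such reads. A length was found for 97.1% of the 11876 tested genes. It is the median over the protein-coding transcripts of a gene, or over all its transcripts where none is coding. Annotated fragments make it short for some genes (633 nt for Myh9, 718 nt for Anln and 567 nt for Tet1), so the length of the longest coding transcript was tried as well.

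Values were analysed as log2(FPKM + 1) for genes with a mean FPKM of at least 1 over the 6 libraries, which left out 6512 genes. A fold change is on that scale and understates the change of low genes. PFOA was compared with DMSO in limma 3.58.1 (R 4.3.3) with an intensity trend in the prior variance, two-sided, and Benjamini-Hochberg adjusted p-values under 0.05 were called. Gene lists were written before the data were examined. Of 23 lists, 22 had at least 5 tested members and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with an estimated correlation and the rotation test fry beside it. Mitochondrially encoded genes were on the other list and are not analysed here. Genes were also adjusted over the members of their list alone, which corrects neither over all genes nor across the 22 lists. A list's median per library is given relative to the DMSO mean. Exact permutation tests of list means used the 10 distinct splits of 6 libraries, which cannot give a two-sided p below 0.1.

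Genes are named by a rule fixed before the data were examined: Myc and Cdh1 whatever their values; the 10 largest changes in each direction among genes past the threshold whose groups do not overlap, leaving out predicted genes; and the members of each list with the smallest adjusted p, up to 4 for lists past the threshold and for the MYC, junction and polarity lists, and up to 2 for other lists. Genes named outside it are examples of transcript length, genes that set DMSO 1 and 2 apart with their parent genes, and members of the fibroblast list. The fit was tested on simulated data with the real means and a spread drawn from the fitted prior variance. Of 2000 genes changed by 1.25-fold, 1.5-fold and 2-fold in 10 runs of 11876 genes, 42.9%, 90.7% and 98.95% were called, with 5.3%, 5.2% and 4.95% of calls false. Genes were drawn independently, without the correlation between genes, the length trend or the difference of DMSO 1 and 2 in the real data. The shares may therefore not carry over to the real libraries. A first version of that simulation drew too little noise and was replaced.

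Alternatives fixed before the data were examined were 2 other pseudocounts (0.1 and 5), 2 other filters (none, and a mean FPKM of at least 5), quantile normalization, median-ratio scaling, 2 other variance models, library weights, the replicate number as a block, a 2-fold threshold, an estimated correlation and leaving out each of the 6 libraries. Another 5 were chosen after seeing the data: removal of a per-library trend (loess, span 0.4, fitted on genes outside all lists) on transcript length, on the length of the longest transcript or on GC content, a fit without both DMSO 3 and PFOA 1, and a term that sets DMSO 1 and 2 against the other 4 libraries. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 handled tables and figures.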

Results

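Gene expression was measured by RNA-seq in morula-like aggregates of mouse expanded pluripotent stem cells, in 3 vehicle-treated (DMSO) and 3 PFOA-treated libraries. PFOA, perfluorooctanoic acid, is a persistent fluorinated surfactant. The series title names c-MYC in the compaction of the embryo, so the comparison of PFOA with DMSO bears on Myc, its targets and the adhesion and polarity genes of compaction. Between 16823 and 16913 genes had an FPKM above 0 in each library, and FPKM summed to between 641975 and 657239 in DMSO and between 585739 and 630644 in PFOA. Spearman's rho between libraries, across genes, was 0.989 to 0.990 within DMSO, 0.990 to 0.991 within PFOA and 0.988 to 0.991 between the groups. The depth of the libraries is unknown.

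Differences between PFOA and DMSO were small. Bri3, which encodes a small transmembrane protein, was the single gene past the threshold among 11876 tested: it fell from 70.0 ± 3.8 FPKM in DMSO to 49.5 ± 1.1 in PFOA (SD, n = 3 each; log2 fold change −0.49, SE 0.047, limma with Benjamini-Hochberg adjusted p = 0.045). No gene was called higher (0 genes), while 1016 genes were higher and 1489 lower at an unadjusted p under 0.05 in limma. Quantile normalization turned these into 1362 higher and 1114 lower. The median absolute log2 fold change was 0.076 and the median half-width of the 95% confidence interval was 0.14. Bri3 was 65.7 FPKM in DMSO 3 and 48.7, 50.8 and 49.1 in the PFOA libraries. With a term for DMSO 1 and 2, chosen after the data were seen, its log2 fold change was −0.40. That fit leaves DMSO 3 as the sole control, so a missed threshold there does not tell whether a gene differs. Bri3 missed the threshold without DMSO 1 (limma, adjusted p = 0.314), DMSO 2 (0.198), PFOA 1 (0.114) or PFOA 3 (0.143). The same held without the filter on low values (0.156), without the variance trend (0.19) and with the replicate number as a block (0.169). It also held with a trend on the length of the longest transcript removed (log2 fold change −0.35, SE 0.042, limma adjusted p = 0.196). Bri3 passed without DMSO 3 (limma, adjusted p = 0.0019), without PFOA 2 (0.032), without both DMSO 3 and PFOA 1 (0.0039) and with library weights (0.026). In fits chosen after the data were seen, it also passed with the trend on GC content (0.029) or on median transcript length (0.041) removed. Without DMSO 3 the counts were 13 higher and 42 lower, and without PFOA 2 they were 2 and 68. Without both DMSO 3 and PFOA 1, a fit added after the data were seen, they were 10 and 42. Genes that set DMSO 1 and 2 apart, such as Rpl31-ps12, were among those called in both fits without DMSO 3.

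**Figure D1:**
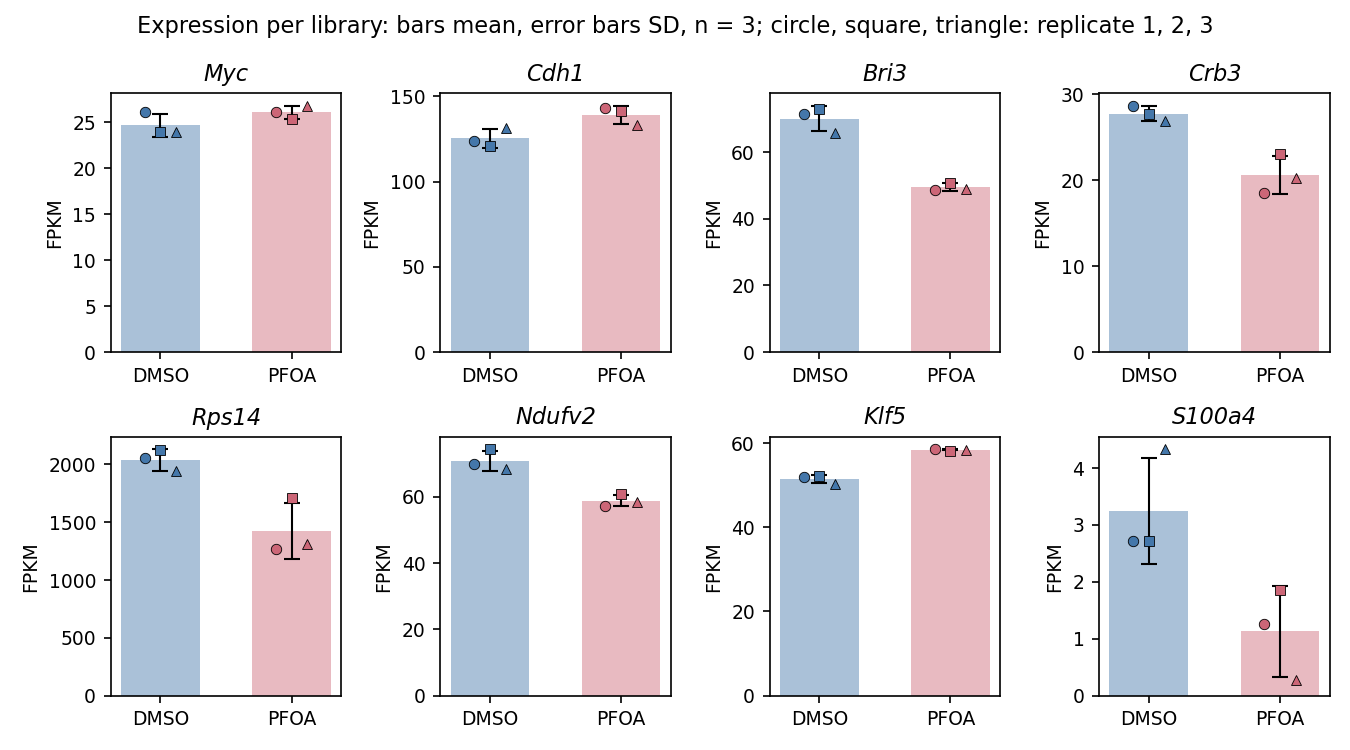
FPKM of 8 genes in the 3 DMSO (blue) and 3 PFOA (red) libraries; bars are means, error bars SD (n = 3), and circles, squares and triangles are replicates 1, 2 and 3. Bri3 values were 65.7 to 73.0 in DMSO and 48.7 to 50.8 in PFOA, whereas the Myc ranges of the groups overlap.

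Myc transcript did not pass the test. It was 26.1, 23.9 and 24.0 FPKM in DMSO 1 to 3 and 26.1, 25.4 and 26.8 in PFOA 1 to 3, that is 24.7 ± 1.3 against 26.1 ± 0.71 (SD, n = 3 each; log2 fold change 0.077, 95% confidence interval −0.030 to 0.19, limma with Benjamini-Hochberg adjusted p = 0.375). Of 15 tested genes of the MYC-MAX network, the transcription factors that pair with MAX or its relatives, 8 were higher and 7 lower, and 0 passed when adjusted over the list alone (camera adjusted p = 0.81; median 0.0093, mean −0.00031). Mlxip was 8.85 ± 0.16 in DMSO and 10.1 ± 0.97 in PFOA. Mga was 16.4 ± 0.64 and 18.2 ± 1.5, Mxd3 3.76 ± 0.22 and 3.06 ± 0.54, and Max 68.7 ± 1.9 and 65.0 ± 2.0. Among 61 tested MYC target genes, 22 were higher and 39 lower, with a median log2 fold change of −0.038 (camera adjusted p = 0.15; adjusted p = 0.668 with an estimated correlation), and 0 passed adjusted over the list alone. Hexokinase 2 (Hk2) was 29.6 ± 1.7 in DMSO and 34.4 ± 2.0 in PFOA. The ribosome biogenesis factor Utp20 was 29.8 ± 1.2 and 34.4 ± 2.3, prohibitin (Phb) 168 ± 3.3 and 151 ± 7.7, and Cbx3 151 ± 4.3 and 138 ± 3.0. Quantile normalization turned the target list's median to 0.0098 (camera adjusted p = 0.83). With the term for DMSO 1 and 2, which leaves DMSO 3 as the sole control, it was −0.0099.

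Transcripts of the cytosolic ribosomal proteins fell in PFOA: 73 of 76 were lower, with a median log2 fold change of −0.17 (−11.3%), with a camera adjusted p of 8.9e-15 (adjusted p = 0.587 with an estimated correlation). Adjusted over the list alone 23 fell, against 0 over all genes. Rps14 was 2039 ± 92 FPKM in DMSO and 1428 ± 241 in PFOA. Rps18 was 2598 ± 50 and 2015 ± 174, Rps19 1173 ± 31 and 952 ± 32, and Rpl34 104 ± 8.0 and 72.1 ± 9.5 (SD, n = 3 each). Ribosomal protein transcripts made up 25.6%, 25.8% and 25.6% of all FPKM in DMSO 1 to 3 and 22.9%, 25.2% and 24.4% in PFOA 1 to 3. Nuclear-encoded subunits of the mitochondrial respiratory chain fell as well: 51 of 53 were lower, with a median of −0.16 (−10.6%), and 27 fell adjusted over the list alone (camera adjusted p = 1.6e-12; adjusted p = 0.587 with an estimated correlation). The complex III iron-sulfur protein Uqcrfs1 was 73.7 ± 2.4 in DMSO and 62.5 ± 0.86 in PFOA. Ndufv2 of complex I was 70.8 ± 3.1 and 58.8 ± 1.8. Cytochrome c (Cycs) was 59.0 ± 2.0 and 47.4 ± 5.1, and Atp5pb of the ATP synthase 302 ± 7.9 and 266 ± 10. The oxidative stress (NRF2) list fell less: 27 of 34 were lower, with a median of −0.081 (camera adjusted p = 0.0052; adjusted p = 0.587 with an estimated correlation). Adjusted over the list alone 1 gene fell, Taldo1 of the pentose phosphate pathway, from 169 ± 2.4 to 149 ± 4.9. On that list the peroxide reductase Prdx6 was 152 ± 4.2 and 138 ± 0.90. The lipid peroxidase Gpx4 was 926 ± 15 and 743 ± 97, and Gclm, of glutathione synthesis, 57.3 ± 1.5 and 52.8 ± 0.13.

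The ribosomal list also passed camera in 7 of the 9 other splits of the libraries into 3 and 3. The smallest adjusted p was 4.1e-16, at a median of 0.13, where the side with more PFOA libraries was the lower. With DMSO 1, DMSO 3 and PFOA 1 against the rest, the side with more PFOA libraries was the higher (median 0.039, camera adjusted p = 0.037). Each other split keeps most libraries of a group on the same side, so part of any treatment difference stays in it. Passing there therefore cannot show whether the camera p is specific to the treatment. The respiratory chain list passed in 6 of the 9. The rotation test fry, for a shift in 1 direction, called 0 of the lists, with adjusted p = 0.192 for the ribosomal proteins, 0.192 for the respiratory chain and 0.178 for the NRF2 list. Its mixed form, which asks whether genes of a list change in either direction and does not compare them with other genes, called 15 of 22 lists, with adjusted p = 0.030, 0.0296 and 0.029 for these 3. The ribosomal, respiratory chain and NRF2 lists were lowest in PFOA 1. The per-library medians, relative to the DMSO mean, were −0.010, 0.022 and −0.015 in DMSO and −0.32, −0.089 and −0.14 in PFOA for the ribosomal proteins. For the respiratory chain they were 0.015, 0.012 and −0.023 against −0.25, −0.093 and −0.12. The two-sided exact permutation p was 0.1 for each of the 3 lists, the smallest that 3 against 3 libraries can give. Without PFOA 1 the ribosomal median was −0.099 and the respiratory chain median −0.090. Under quantile normalization they were −0.029 (camera adjusted p = 0.024) and, for the Mitochondrial respiratory chain, nuclear-encoded list, −0.0954, while the NRF2 list missed the threshold (−0.025, adjusted p = 0.171). Within the 4 libraries outside DMSO 1 and 2, DMSO 3 is the sole control and is assumed to vary like the other libraries. The medians there were −0.17 for the ribosomal proteins (camera adjusted p = 4.3e-14), −0.13 for the respiratory chain (2.6e-11) and −0.050 for the NRF2 list (0.087, no longer past the threshold). With an estimated correlation the adjusted p was 0.659 for each.

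Transcript length moved with the groups. Genes outside the lists with transcripts under 1000 nt had a median log2 fold change of −0.071, and 71.5% of 2030 were lower in PFOA, whereas those of at least 4000 nt had a median of 0.076, with 17.1% of 1851 lower. Across genes, which are not independent replicates, Spearman's rho between length and fold change was 0.452. The short genes' medians were 0.0098, 0.0079 and −0.018 in DMSO 1 to 3 and −0.12, −0.045 and −0.049 in PFOA 1 to 3. The ribosomal and respiratory chain lists had median lengths of 713 and 710 nt and the NRF2 list 1526 nt. With a per-library length trend removed, a fit added after the data were seen, their medians were −0.11 (camera adjusted p = 1e-11), −0.097 (6e-08) and −0.055 (0.025). That length is the median over the coding transcripts of a gene. The length of the longest coding transcript followed the fold change more closely (Spearman's rho 0.598), and the 606 genes outside the lists under 1000 nt by it had a median of −0.16, with 84.98% lower. With a trend on this length removed, also added after the data were seen, the Cytosolic ribosomal proteins list was at −0.034 (camera adjusted p = 0.015), with 48 of 76 genes lower and an SD of 0.13 between members, against 0.12 before. The Mitochondrial respiratory chain, nuclear-encoded list was at −0.027 (0.081, no longer past the threshold), with 36 of 53 lower, and the Oxidative stress (NRF2) response list at −0.0054 (0.294, no longer past it). The ribosomal medians were then −0.026, 0.0076 and 0.014 in DMSO and −0.094, −0.0054 and −0.024 in PFOA, so the groups overlapped. Those of the respiratory chain were 0.0020, −0.0025 and 0.0023 against −0.041, −0.026 and −0.017, so each PFOA library stayed below each DMSO library. With the trend on the median length removed the groups stayed apart for both lists: −0.024, 0.015 and 0.0052 against −0.22, −0.051 and −0.092 for the ribosomal proteins, and 0.0020, 0.0081 and −0.0032 against −0.15, −0.058 and −0.073 for the respiratory chain. Of the genes past the threshold over their list alone, 14 of 23 ribosomal protein genes passed in the same way with the median length removed and 11 with the longest. For the respiratory chain it was 10 and 5 of 27, for polarity 6 and 3 of 8, for naive pluripotency 4 and 3 of 6, for p53 targets 2 and 2 of 3 and for fibroblast markers 1 and 1 of 2. The respiratory chain counts include Atp5pb, for which no length was found and whose value the removal left unchanged. It was 0 for the NRF2, primitive endoderm, extracellular matrix and neural lists.

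**Figure D2:**
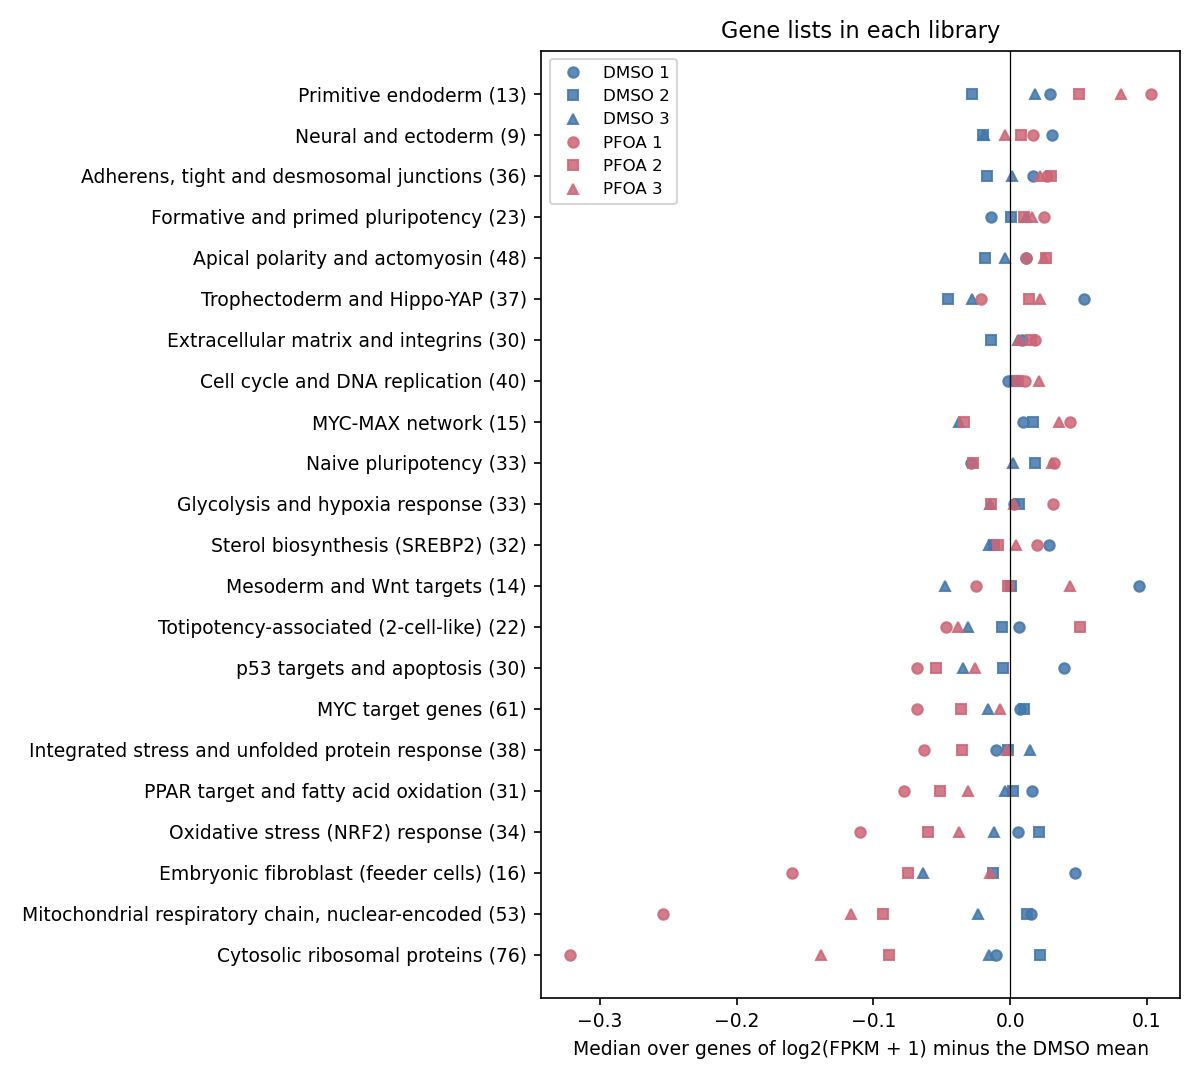
Median of each gene list in each library, as log2(FPKM + 1) minus the DMSO mean, with DMSO in blue and PFOA in red and the number of tested genes in brackets. The ribosomal protein medians were −0.32, −0.089 and −0.14 in PFOA 1 to 3 and between −0.015 and 0.022 in DMSO.

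**Figure D3:**
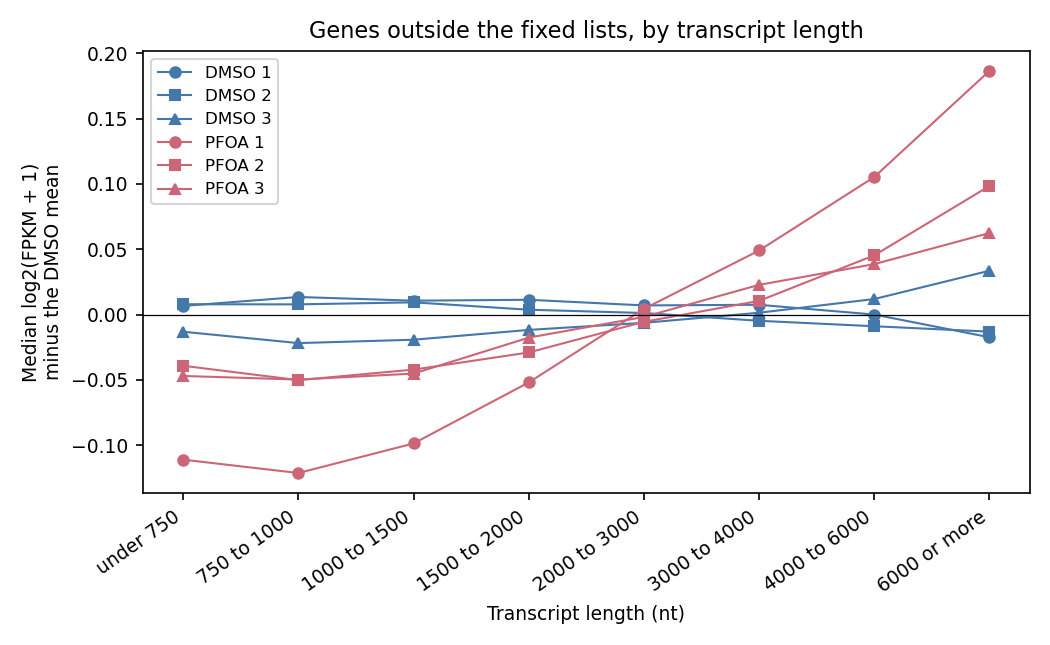
Median log2(FPKM + 1) minus the DMSO mean, per library, of genes outside the lists grouped by transcript length in nt. For transcripts of 6000 nt or more the PFOA medians were 0.19, 0.098 and 0.062, and for those under 750 nt −0.11, −0.039 and −0.047.

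Cadherin 1, the adhesion molecule through which blastomeres flatten at compaction, did not pass the test: Cdh1 was 125 ± 5.6 FPKM in DMSO and 139 ± 5.4 in PFOA (SD, n = 3 each; log2 fold change 0.15, 95% confidence interval 0.044 to 0.25, limma with Benjamini-Hochberg adjusted p = 0.15), with each PFOA value above each DMSO value. Chance separates the groups in this way, in either direction, for 10% of genes. DMSO 3 was 132 and the PFOA libraries were 143, 141 and 133. With the term for DMSO 1 and 2, which leaves DMSO 3 as the sole control, the log2 fold change was 0.078. Of 36 junction genes 20 were higher and 16 lower, and 0 passed adjusted over the list alone (camera adjusted p = 0.167). Vinculin (Vcl) was 18.8 ± 0.34 in DMSO and 21.5 ± 1.2 in PFOA. Desmoplakin (Dsp) was 7.96 ± 0.43 and 9.27 ± 0.38, p120-catenin (Ctnnd1) 64.3 ± 1.2 and 69.8 ± 1.1, and the tight junction scaffold Tjp1 41.3 ± 1.5 and 46.3 ± 2.4. Of 48 genes of apical polarity and actomyosin, 29 were higher and 19 lower (camera adjusted p = 0.121). Adjusted over the list alone 5 rose and 3 fell, against 0 over all genes. Among them Crb3, an apical Crumbs protein, fell from 27.7 ± 0.87 to 20.6 ± 2.3 and the GTPase Rhoc from 55.3 ± 2.8 to 47.1 ± 2.1. Moesin (Msn) rose from 49.97 ± 0.33 to 55.5 ± 0.14 and the myosin light chain Myl9 from 3.31 ± 0.082 to 4.11 ± 0.035. Quantile normalization took the polarity list past the threshold (median 0.071, camera adjusted p = 0.0057). With the length trend removed the polarity median was 0.011 (camera adjusted p = 0.075) and the junction median 0.013 (0.261). Crb3, Rhoc, Msn and Myl9 each still passed over the list with that trend removed. With the trend on the longest transcript removed, Rhoc did not (limma, adjusted p = 0.129) and the other named polarity genes did. The transcripts of Dsp, Ctnnd1 and Tjp1 are long (8676.5, 5953 and 6102 nt), and long transcripts were higher in general.

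Pluripotency and lineage lists did not pass the camera test. Under quantile normalization the Naive pluripotency list did (median 0.064, camera adjusted p = 0.025), as it did with a trend on the longest transcript removed (0.043, 0.015). For naive pluripotency 17 of 33 genes were higher (camera adjusted p = 0.408). Adjusted over the list alone 5 rose and 1 fell, against 0 over all genes, which held for every list. Klf5 rose from 51.5 ± 0.96 to 58.4 ± 0.13, and the demethylation enzyme Tet2 from 17.8 ± 0.96 to 22.0 ± 1.9. Of 13 primitive endoderm genes 8 were higher (camera adjusted p = 0.121) and 4 rose adjusted over the list alone, including the basement membrane genes Lama1, from 6.28 ± 0.26 to 7.66 ± 0.28, and Col4a2, from 5.65 ± 0.19 to 6.75 ± 0.17. Their transcripts are long (9526 and 6450 nt), and with the length trend removed their log2 fold changes went from 0.25 and 0.22 to 0.11 and 0.13, which did not pass (limma, adjusted p = 0.191 and 0.171 over the list). That list passed without PFOA 1 (median 0.10, adjusted p = 0.033), with a mean FPKM of at least 5 (0.14, 0.021) and without both DMSO 3 and PFOA 1 (0.13, 0.049). The trophectoderm and Hippo-YAP list had 22 of 37 genes higher (camera adjusted p = 0.608), with Lgals3 at 47.2 ± 2.3 and 39.1 ± 4.2 and Tead1 at 34.7 ± 1.5 and 39.9 ± 2.9 FPKM in DMSO and PFOA. Formative and primed pluripotency had 13 of 23 higher (0.63; test and median up, mean −0.0022), with Etv5 at 72.7 ± 1.7 and 79.2 ± 1.0 and Nodal at 44.1 ± 0.34 and 40.1 ± 2.3. The 2-cell-like list had 9 of 22 higher (0.835), and its members Zscan4c, 19.8 ± 1.5 and 23.1 ± 1.1, and Gm2022, 26.4 ± 1.5 and 23.5 ± 1.2, share at least 85.5% of their 50-nt words with other genes. Mesoderm and Wnt targets had 6 of 14 higher (0.812; test up, median −0.0047), with Znrf3 at 5.21 ± 0.20 and 5.78 ± 0.14 and Rnf43 at 1.16 ± 0.070 and 1.34 ± 0.15. For neural and ectoderm genes 6 of 9 were higher (0.959), and 1 fell adjusted over the list alone, Tubb3, from 27.0 ± 0.52 to 24.1 ± 0.82. Stmn2 was 69.9 ± 1.4 and 66.3 ± 4.1.

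PPAR targets and fatty acid oxidation genes, listed because PFOA is a known ligand of PPARα, were lower for 26 of 31 with a median of −0.063, which did not pass (camera adjusted p = 0.121; median length 1783 nt), and 0 passed adjusted over the list alone. Without the filter on low values the PPAR target and fatty acid oxidation list passed (median −0.063, camera adjusted p = 0.018). Acaa1b was 1.32 ± 0.18 in DMSO and 0.85 ± 0.085 in PFOA and Eci1 28.9 ± 2.2 and 25.6 ± 0.58. Of 30 p53 target and apoptosis genes 21 were lower (camera adjusted p = 0.157) and 3 fell adjusted over the list alone, among them Phlda3, from 75.4 ± 3.8 to 59.0 ± 2.2, and Gadd45g, from 11.6 ± 1.3 to 8.46 ± 0.34. The integrated stress and unfolded protein response list had 24 of 38 lower (0.293), with the transcription factor Atf5 at 10.2 ± 0.97 and 8.05 ± 0.11 and Psph at 24.8 ± 0.69 and 22.1 ± 0.96. Glycolysis and hypoxia had 17 of 33 higher (0.585), with Pdk1 at 9.94 ± 0.56 and 11.7 ± 1.0 and Higd1a at 9.45 ± 0.79 and 8.04 ± 0.45. Sterol synthesis had 15 of 32 higher (0.812; test up, median −0.0021), with Scd1 at 19.0 ± 0.27 and 21.9 ± 1.1 and Acaca at 15.2 ± 0.57 and 17.5 ± 0.95. Cell cycle and DNA replication had 21 of 40 higher (0.585), with Gins2 at 44.1 ± 1.1 and 39.5 ± 0.94 and Foxm1 at 26.3 ± 0.064 and 29.6 ± 1.2. Extracellular matrix and integrins had 16 of 30 higher (camera adjusted p = 0.16), and 2 rose adjusted over the list alone, the basement membrane genes Nid1, from 22.2 ± 0.77 to 25.5 ± 0.69, and Agrn, from 55.3 ± 0.30 to 61.0 ± 1.4. Their transcripts are long (6091 and 7042 nt), and genes outside the lists of at least 6000 nt had a median log2 fold change of 0.11, with 8.8% lower. With the length trend removed Nid1 went from 0.19 to 0.10 and Agrn from 0.14 to 0.035, which did not pass (limma, adjusted p = 0.201 and 0.506 over the list). The Extracellular matrix and integrins list passed with a mean FPKM of at least 5 (median 0.023, camera adjusted p = 0.038) and with the GC trend removed (0.037, 0.049), and its median was −0.0059 with the length trend removed (0.861). Under quantile normalization the Glycolysis and hypoxia response list (median 0.055, camera adjusted p = 0.0475) and the Cell cycle and DNA replication list (0.056, 0.011) passed. Markers of embryonic fibroblasts, used as feeder cells in stem cell culture, were lower for 11 of 16 genes (camera adjusted p = 0.121), and 2 fell adjusted over the list alone: Twist2, from 1.95 ± 0.27 to 1.11 ± 0.072, and S100a4, from 3.25 ± 0.94 to 1.13 ± 0.80. The Embryonic fibroblast (feeder cells) list passed under quantile normalization (median −0.10, camera adjusted p = 0.025), without PFOA 3 (−0.13, 0.0495) and with the trend removed on the median (−0.092, 0.025) or the longest (−0.089, 0.021) transcript length. The fibroblast list's medians per library were 0.047, −0.013 and −0.064 in DMSO and −0.16, −0.075 and −0.015 in PFOA. With the term for DMSO 1 and 2, which leaves DMSO 3 as the sole control, the list's median log2 fold change was −0.0070.

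DMSO 1 and 2 stood apart from DMSO 3 and the PFOA libraries. Between them and the other 4 libraries, 11 genes had a gap of over 2-fold, against at most 2 genes in the other 14 divisions of 2 against 4 libraries and 0 genes for DMSO against PFOA. The genes below were chosen after their values were seen. The pseudogene Rpl31-ps12 was 64.4 and 59.5 FPKM in DMSO 1 and 2, 0 in DMSO 3 and 0, 0.48 and 0.35 in PFOA 1 to 3. Rpl37rt, a retrotransposed copy of Rpl37, was 333 and 329 in DMSO 1 and 2 and 144 to 160 in the others, where Rpl37 was 550 and 515 against 565 to 704. Llph-ps2 was 90.3 and 94.4 against 37.2 to 43.5, where Llph was 52.7 and 56.6 against 75.6 to 90.9. On the first principal component, which held 45.2% of the variance, DMSO 1 to 3 lay at −12.5, −10.02 and 0.96 and PFOA 1 to 3 at 13.02, 3.99 and 4.55. With the term for DMSO 1 and 2, DMSO 3 is the sole control, so a gene missing the threshold there does not tell whether it differs.

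**Figure D4:**
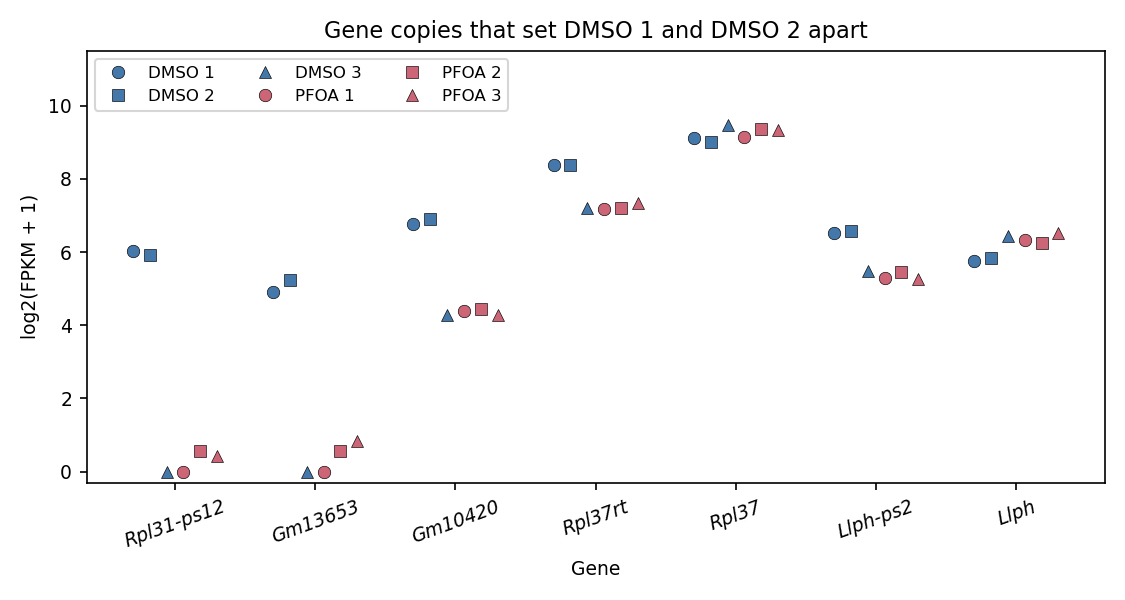
Expression as log2(FPKM + 1) of 7 genes, gene copies and their parent genes, in each library. Rpl31-ps12 was 64.4 and 59.5 FPKM in DMSO 1 and 2 and at most 0.48 in the other 4 libraries.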

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

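The fits without the length trend (by the median or the longest transcript) or the GC trend, without both DMSO 3 and PFOA 1, and with the term for DMSO 1 and 2 were chosen after the data were seen. Myc stayed higher in PFOA and short of the threshold under each alternative, with log2 fold changes of 0.057 to 0.118 as single libraries were left out. The single gene Mga went from a log2 fold change of 0.138 to −0.033 with the length trend removed (limma, adjusted p = 0.751), and to −0.023 with the trend on the longest transcript removed (0.851), where Gm2022 turned to 0.059. The number of genes called higher was 0 to 13 and of genes called lower 0 to 68 as single libraries were left out, and the 55 genes called without DMSO 3 and the 70 called without PFOA 2 shared 5. Without both DMSO 3 and PFOA 1 there were 10 higher and 42 lower. Genes called lower numbered 0 with no filter on low values, where more genes were tested, 0 without the variance trend, 0 with the term for DMSO 1 and 2, 0 with the trend on the longest transcript removed, and 0 at a 2-fold threshold. They numbered 2 with library weights and 2 with the GC trend removed. Without DMSO 3, only DMSO 1 and 2 stand for the controls. The smallest adjusted p there were those of Gm10420, Gm14279, Rpl31-ps12, Rpl37rt, Gm13653 and Llph-ps2 (limma, 1.6e-06 to 0.00021). In the main fit they were 0.142 to 0.211. These genes set DMSO 1 and 2 apart, so their calls cannot be told apart from the difference of that pair. The term for DMSO 1 and 2 leaves DMSO 3 as the sole control, so nothing is read from its 0. Apart from this and the filter, the cause was not tested. Pairing by replicate number was not seen. The deviations of same-numbered libraries correlated at −0.11, −0.0095 and −0.14, and 0 of 6 libraries correlated best with its own number. DMSO 3 and PFOA 1 stand apart within their groups and bear different numbers, so these correlations cannot exclude a pairing. With the replicate block, 0 genes were called higher and 0 lower and 3 lists passed, with Bri3 at an adjusted p of 0.169 (limma). Lists past the threshold numbered 3 to 4 as single libraries were left out, 5 with a mean FPKM of at least 5, 7 with quantile normalization and 0 with an estimated correlation; the cause was not tested. The MYC target median was −0.057 to −0.018 as single libraries were left out.

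The Cytosolic ribosomal proteins list had medians of −0.23 to −0.029 over the alternatives, with a camera adjusted p under 0.05 in each at the preset correlation, and the Mitochondrial respiratory chain, nuclear-encoded list −0.18 to −0.027, which missed it with the trend on the longest transcript removed (0.081). That p is of little use here, since neither list passed with an estimated correlation (camera adjusted p = 0.587 for each). Other splits of the libraries passed as well, but they keep part of any treatment difference and cannot decide this. The ribosomal median shrank from −0.17 to −0.029 under quantile normalization and to −0.034 with the trend on the longest transcript removed. In that fit the ribosomal SD between members was 0.13 against 0.12 before, so the median shrank and the spread did not grow much. The Oxidative stress (NRF2) response list missed the threshold in that fit (−0.0054, 0.294). List medians close to 0 that did not pass changed sign as follows, and the cause was not tested. With no filter, mesoderm and Wnt was 0.0017, neural −0.0053, glycolysis −0.0099 and extracellular matrix −0.0011; with a mean FPKM of at least 5, glycolysis was −0.0099. With quantile normalization the MYC targets were at 0.0098, mesoderm and Wnt at 0.015, integrated stress at 0.010 and sterol synthesis at 0.022, and with median-ratio scaling the Sterol biosynthesis (SREBP2) list was at 0.00088. With library weights, naive pluripotency was −0.016, the Glycolysis and hypoxia response list −0.0037 and the Cell cycle and DNA replication list −7.8e-05. With the length trend removed, the MYC-MAX network was −0.011, 2-cell-like 0.020, mesoderm and Wnt 0.00014, neural −0.027 and extracellular matrix −0.0059. With the trend on the longest transcript removed, the MYC target genes list was 0.0062, the MYC-MAX network list −0.015, the Totipotency-associated (2-cell-like) list 0.072, the Mesoderm and Wnt targets list 0.0040, the Neural and ectoderm list −0.0083 and the Extracellular matrix and integrins list −0.023. With the GC trend removed, mesoderm and Wnt was 0.014 and cell cycle −0.0027. Without both DMSO 3 and PFOA 1, the MYC-MAX network was −0.016, trophectoderm −0.0021, naive pluripotency −0.016, mesoderm and Wnt 0.021, glycolysis −0.0053 and cell cycle −0.00087. With the term for DMSO 1 and 2, formative pluripotency was −0.014, mesoderm and Wnt 0.079, neural −0.019 and sterol synthesis 0.017. As single libraries were left out, the Naive pluripotency list ranged from −0.0038 to 0.027, mesoderm and Wnt from −0.021 to 0.046, sterol synthesis from −0.015 to 0.011, and the MYC-MAX network from −0.027 to 0.0044. Trophectoderm ranged from −0.015 to 0.040, the Neural and ectoderm list from −0.0037 to 0.040 and extracellular matrix from −0.0062 to 0.026. Junctions ranged from −0.0025 to 0.043, the Formative and primed pluripotency list from −0.0069 to 0.041, 2-cell-like from −0.046 to 0.0014 and cell cycle from −0.0028 to 0.021. Depth is unknown, so no limit from counting can be set for low genes. In simulated data, with genes drawn independently, 42.9% of genes with the smallest fold change tried were called.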

Other observations

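The family scan, the length, GC and copy tests, the search for libraries that stand apart and the fibroblast test were all chosen after the data were seen. Families of genes that share the letters of their symbol, 75 in all with at least 15 members and histones among them, were compared in the same way as the lists. Of these, 15 passed (7 down, 8 up) and 11 also passed with the trend on the median transcript length removed, 6 with the trend on the longest removed (Rps, Mrps, Nudt, Cep, Ddx and Nup), and 0 passed with an estimated correlation (smallest adjusted p = 0.559). Among the families not yet described, mitochondrial ribosomal proteins were lower. The large subunit family Mrpl was lower for 49 of 49 genes with a median log2 fold change of −0.11 (camera adjusted p = 3.5e-09) and the small subunit family Mrps for 27 of 29 with −0.13 (8.8e-08). With the trend on median length removed they were −0.090 (4.3e-06) and −0.10 (8.7e-06), and by the longest transcript −0.045 (0.065, no longer past the threshold) and −0.056 (0.042). Ubiquitin-specific proteases (Usp) were higher for 41 of 53 genes, median 0.066 (camera adjusted p = 8.1e-05), kinesins (Kif) for 28 of 29, median 0.079 (8.1e-05), and centrosomal proteins (Cep) for 31 of 37, median 0.096 (0.00014). With the trend on median length removed Usp was at 0.034 (0.032), Kif at 0.028 (0.053, no longer past the threshold) and Cep at 0.072 (0.0083). The others past the threshold were Rpl, Rps, Cox, Nudt and Tmem, lower, and Kdm, Arhgap, Ddx, Dhx and Nup, higher. Kdm, Dhx and Tmem also lost the call with that trend removed.

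Ribosomal protein and respiratory chain transcripts were lower in PFOA, and short transcripts in general were lower too. A trend on transcript length is a candidate explanation for part or most of the shift, depending on the length used. With it removed by the median transcript, the ribosomal and respiratory chain medians were −0.11 and −0.097, from −0.17 and −0.16. The rule for that test was written before it was run, and by it the result went against length for both lists. By the longest transcript, whose rule was written afterwards, the medians were −0.034 and −0.027. By that rule the result went with length for the respiratory chain and was undecided for the ribosomal list. PFOA and DMSO libraries then overlapped for the ribosomal list and not for the respiratory chain. Of 10000 random lists matched on the longest transcript, 0.35% and 0.92% were as low (0% and 0% by the median transcript). The random lists were matched on length only, while members of the 2 lists vary together (estimated inter-gene correlation 0.65 and 0.47). These shares therefore cannot decide the question. Whether length accounts for all of either shift stays open, and an effect of PFOA, or a difference in RNA or library preparation that acts by length, was not tested. A trend on GC content is argued against as the whole cause, since its removal left −0.18 and −0.16, and so are reads shared with pseudogene copies for the ribosomal proteins: the 23 genes with under 20% of their 50-nt words in other genes were lower in 23 cases, with a median of −0.21, against −0.16 for the other 53. A difference of PFOA 1 alone is argued against as the whole cause before that removal, since without it the medians were −0.099 and −0.090 and the ribosomal medians of PFOA 2 and 3 were −0.089 and −0.14 against −0.015 to 0.022 in DMSO.

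Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. Genes lower numbered 1 in the real split and at most 0 in the others (1 of 10 as large), genes higher 0 and 0 (10 of 10), genes at an unadjusted p under 0.05 2505 and 1041 (1 of 10), and lists past the threshold 3 and 6 (4 of 10). Of the splits that keep DMSO 1 and 2 together, the one with PFOA 3 gave 6 lists, with PFOA 2 it was 3 and with PFOA 1 it was 0. PFOA 1 lay opposite that pair on the first principal component, so these counts cannot tell what the pair accounts for. The ribosomal list passed camera in 7 of the 9 other splits. In 1 of them its median was 0.13 with an adjusted p of 4.1e-16, against −0.17 and 8.9e-15 in the real split. Its median was larger in size in the real split than in the others. The other splits keep most libraries of a group on the same side, so they are not free of a treatment difference.

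The genes with the widest gap between DMSO 1 and 2 and the other libraries include many gene copies, and reads shared between near-identical copies are a candidate explanation for these genes. All 21 genes with a gap of over 0.5 on the log2 scale were tested first: 15 of the 16 with a sequence to search (93.75%) had at least 20% of their 50-nt words in another gene, but 76.2% with a sequence is under the 80% required, so that test is void. The set was then narrowed, after that result was seen, to the 11 genes with a gap of over 2-fold, of which 10 had a sequence and 10 (100%) shared words, against 48 of 587 randomly drawn genes (8.18%; one-sided Fisher's exact test, p = 3.6e-11). The narrowed result is therefore no independent evidence; it fits a difference in how reads were placed among copies, such as another read length or index, and which of these applies was not tested. A batch of culture or of sequencing stays open, since DMSO 1 and 2 are of 1 group. GC content was also compared, across genes, with each gene's deviation from its mean over the libraries. Spearman's rho was 0.27 and 0.15 in DMSO 1 and 2 and −0.0075 in DMSO 3. It was −0.26, −0.077 and −0.0075 in PFOA 1 to 3. PFOA 1 lay apart in the other direction, so these values do not single out DMSO 1 and 2.

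The fibroblast list did not pass the main test (11 of 16 lower, camera adjusted p = 0.121; adjusted p = 0.587 with an estimated correlation), and its median in DMSO 3 (−0.064) was below that in PFOA 3 (−0.015). For the members that were lower, a smaller share of feeder cell RNA is a candidate explanation. With the length trend removed, 87.5% of 16 members were below 0 (median −0.092, camera adjusted p = 0.025) and the 5 most abundant, Tagln, Bgn, Thy1, Dcn and Twist1, were each lower before removal, with a median of −0.19. As first written, the test would have counted this in favour of the explanation. A requirement that members move alike was added after their values were seen, and it was not met (Q = 52.3 for differences among the members, 37.3 with the trend on the median length removed and 32.1 on the longest). With the trend on the median length removed Col1a1 was at −0.096, Col1a2 at −0.055 and S100a4 at −0.99. Before that removal they were at −0.010, −0.038 and −1.05, so Col1a1 and Col1a2 were close to 0 without it. The explanation stays open. With the term for DMSO 1 and 2, which leaves DMSO 3 as the sole control, the list's median was −0.0070.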
